A study of Gallus gallus with 8 samples.

How the data were processed

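The values were the signal intensities that the authors deposited for 8 Affymetrix Chicken Genome Arrays, in arbitrary units and not on a log scale. The submitters' processing notes name MAS5; the software version and the scaling target are not given in the sources used here. Eggs were kept at 38 °C, the endoderm was separated from the mesoderm after dispase treatment, total RNA was prepared with RNeasy, and 5 µg per array was labelled with biotin in a single cycle without amplification. RNA concentrations had been equalized and quality checked on a gel before labelling.

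The design assumed that MAS5 had brought the arrays to a common target. The trimmed means of the columns, 76.3 to 169.7, differed from array to array, so this assumption was not met. The deposited values were nevertheless tested as planned, without scaling between arrays, and each count was set beside its value after quantile normalization. Detection calls were not used.

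The array held 38535 probe sets, of which 96 controls were set aside. Of the other 38439, 27168 carried 1 gene symbol, 177 several and 11094 none in the probe annotation of the array platform; 26853 of those symbols were found in the current chicken reference table and none was changed. Probe sets whose mean signal exceeded the 40th percentile (9.96) were kept, 23063 in all, of which 17981 had 1 symbol, for 10553 genes. Signals were transformed as log2(signal + 16), which understates changes of genes with low signal. Days were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 8 arrays in a single fit, 4 residual and 9.37 prior degrees of freedom (4.71 after quantile normalization) and Benjamini-Hochberg adjustment at 0.05. Comparisons were day 4 with day 1, day 2 with day 1, day 3 with day 2 and day 4 with day 3, besides a moderated F-test over the days. With 2 arrays per day the precision is limited.

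There were 14 gene lists and 6 marker lists, fixed before the data were examined. They covered serum proteins; lipid uptake, synthesis and lipoprotein assembly; cholesterol synthesis; endoderm and hepatic transcription factors; absorptive transporters and peptidases; lysosome and endocytosis; gluconeogenesis and glycogen; cell cycle; pluripotency and epiblast; primitive streak and hypoblast; secreted angiogenic and vascular regulators; ER and secretory pathway; oxidative phosphorylation; detoxification and redox; and erythroid, endothelial, mesoderm, leukocyte, ectoderm and neural markers. Each gene was represented by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 20 lists of a comparison, 80 tests in all, and again with the correlation estimated from the data. Genes shared between lists included APOA1, APOA4, APOB, BMP2, VTN, SERPINF1, LIPA, SNAI2, CA2, TAL1 and LMO2, and the serum protein list held A1CF, which encodes an editing factor of APOB mRNA and not a serum protein.

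Genes were named by a rule: in each comparison the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, separated in both arrays and with 1 symbol that was not a placeholder, up to 4 members of each list with the smallest adjusted p, and up to 4 members of each marker list with the highest signal. Further genes, among them TTR, APOA1, APOB and TF, were taken from the lists after their values were seen.

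The code was tried on simulated arrays with 200 changed probe sets in each of 10 simulations. With variances drawn from the fitted prior, 1.3% of changes of log2 1 and 51.5% of changes of log2 2 were found, and 3.65% of the calls were false. With each probe set's own moderated SD, 8.8% and 84.4% were found and 11.8% of the calls were false, above the nominal 5%. A first version of this trial used a single kind of variance and gave more false calls than the nominal share, and the trial was then widened to both kinds. In a simulated list test the shifted list was found (adjusted p = 6.2e-29) and 0 of 19 unchanged lists were called. Genes were simulated there as independent, while the correlations estimated within the real lists were 0.17 to 0.85. That trial therefore does not show how often unchanged lists would be called in these data.

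Alternatives tried were quantile normalization, a shift of each array to the same median, no intensity trend, a robust trend, the mean of the probe sets of a gene, a pseudocount of 1 or 64, no filter or a 60th percentile filter, array weights, only the 2 days compared, a replicate block, an estimated correlation, a 2-fold minimum and each array left out. Scaling by hybridization or poly-A controls, the array pairs left out together and 7 gene families were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.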

Results

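Transcript levels were measured in the endoderm of the chicken yolk sac on embryonic days 1, 2, 3 and 4. The yolk sac endoderm is the extraembryonic epithelium that faces the yolk, takes up its lipids and proteins and makes serum proteins before the liver does. Each day was represented by 2 independent total RNA samples, each hybridized to its own Affymetrix Chicken Genome Array, which gave 8 arrays. Each sample was itself a pool of tissue collected at 4 h intervals across the day, after the endoderm had been separated from the mesoderm with dispase. The design sets the days against each other, and thereby asks which transcripts the tissue gains and loses as it begins to supply serum proteins and lipids to the embryo. Because the 2 samples of a day are pools, the p-values measure the spread between pooled samples and not between single embryos.

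The deposited signals were not on one common level. The mean signal after trimming 2% of the probe sets at each end was 105 and 169.7 on the arrays of day 1, 106 and 90.0 on day 2, 90.9 and 91.9 on day 3, and 76.3 and 83.7 on day 4. Day 1 replicate 2 was therefore the brightest array. The ratio of the 3' to the 5' signal of beta-actin, an index of RNA integrity and labelling length, was 2.907 and 1.498 on day 1, 1.74 and 3.77 on day 2, 2.63 and 3.36 on day 3, and 4.30 and 3.22 on day 4. The median log2 change of all 23063 probe sets tested was -0.55 from day 1 to day 4 as deposited and 0.01 after quantile normalization, so each count over all genes below is followed by its value after quantile normalization. In a principal component analysis the first component held 66.8% of the variance and placed both day 1 arrays on one side and all arrays of days 3 and 4 on the other. Group values are mean signals ± SD of the 2 arrays of a day, and log2 changes, on the log2(signal + 16) scale, carry their SE and an adjusted p from limma. The lower a gene's mean on either day, the more the size of its change depends on the 16 added, most of all below the filter signal of 9.96. The camera test sets a list against all other genes, so a list with a median or mean below 0 can be placed up where other genes fell more.

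Between day 1 and day 4 the genes with the largest rises included AFP and ALB, for plasma proteins, and OTC and CPS1, for enzymes of the urea cycle. Those with the largest falls included CA2, for a carbonic anhydrase, and the homeobox genes CDX4 and HHEX. AFP, which encodes alpha-fetoprotein, the main plasma protein of the early embryo, had a mean signal of 5.24 ± 2.33 on day 1 and 8319.6 ± 3010.0 on day 4, a log2 rise of 8.57 ± 0.30 (adjusted p = 4.7e-09). OTC and CPS1, which encode the mitochondrial enzymes of the urea cycle, rose by 5.42 ± 0.54 (adjusted p = 6.7e-05) and 5.06 ± 0.36 (adjusted p = 6.0e-06). ALB, for serum albumin, rose from 26.3 ± 11.1 to 2465 ± 2687, and its signals on the 2 arrays of day 4 were 4366 and 565. The other largest rises were those of PTGDS (5.04 ± 0.53), the globin gene HBBR (4.92 ± 0.64), the inter-alpha-trypsin inhibitor gene ITIH2 (4.89 ± 0.31) and GC (4.82 ± 0.42), which encodes the vitamin D-binding protein.

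The largest falls over the same interval, on the log2(signal + 16) scale, were in CA2, CDX4, HHEX, LMO2, CFC1, CXCL12, BHLHE22 and SNAI2. Of these, CA2, LMO2 and SNAI2 are also in the preset erythroid, endothelial or mesoderm marker lists. The mean signal on day 1 was 1568 for LMO2 and 742 for SNAI2. Whether the falls came from endoderm or from other cells present on day 1 was not tested. The carbonic anhydrase gene CA2 went from 4003 ± 781 to 27.1 ± 3.96, a log2 change of -6.53 ± 0.83 (adjusted p = 0.00034). CDX4, a caudal-type homeobox gene of the posterior embryo, changed by -5.99 ± 0.43 (adjusted p = 6.0e-06), and HHEX, a homeobox gene of endoderm and of endothelial precursors, by -5.94 ± 0.96 (adjusted p = 0.0013). LMO2, a cofactor needed for blood and vessel formation, changed by -5.83 ± 1.02, CFC1, a co-receptor for Nodal, by -5.71 ± 0.91, and the chemokine gene CXCL12 by -5.57 ± 0.98. The fall of SNAI2, a gene of epithelial to mesenchymal transition, was -5.28 ± 1.35 (adjusted p = 0.012), and it missed the threshold after quantile normalization (adjusted p = 0.065). CFC1, BHLHE22 and SNAI2 had means of 2.15, 8.33 and 3.01 on day 4, below the filter signal of 9.96. AFP and OTC had means of 5.24 and 1.16 on day 1, also below it. LMO2 and CDX4 had means of 12.1 and 16.4 on day 4. The sizes and ranks of these changes depend on the 16 added before the logarithm. Those of CA2, HHEX, ALB and CPS1, whose lower means were 26.3 to 31.3, depend on it to a lesser degree.

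Serum protein genes had the highest median change of the 20 preset lists. Of 34 measured members 24 rose and 1 fell, and adjusted over the list alone 28 rose and 1 fell. After quantile normalization 29 rose and none of the other 5 fell. The fall as deposited was that of PIT54, named here after its value was seen, which encodes a hemoglobin-binding protein of avian plasma. Besides AFP and ITIH2, SERPIND1, for heparin cofactor, rose from 315 ± 45.2 to 5852 ± 1196 and APOA4 from 397 ± 116 to 5816 ± 1552. The list had a median log2 change of 2.13 against -0.66 over all genes. The camera test with its preset correlation gave an adjusted p of 7.6e-35, which was lost with an estimated correlation (adjusted p = 0.40 with an estimated correlation). TTR, APOA1 and APOB did not pass the test (adjusted p = 0.99, 0.52 and 0.17), APOB passed after quantile normalization (adjusted p = 0.023), and their signals lay between 7252 and 10580 on all 8 arrays, near the highest signal of any probe set, which was 11415 to 13740 by array. The globin genes HBBR, HBZ, HBE and HBA1 rose as well, HBZ from 460.0 ± 469 to 3789 ± 1626, while the 18 primitive erythroid markers as a list had 6 rises and 6 falls and a median of -0.28.

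**Figure D1:**
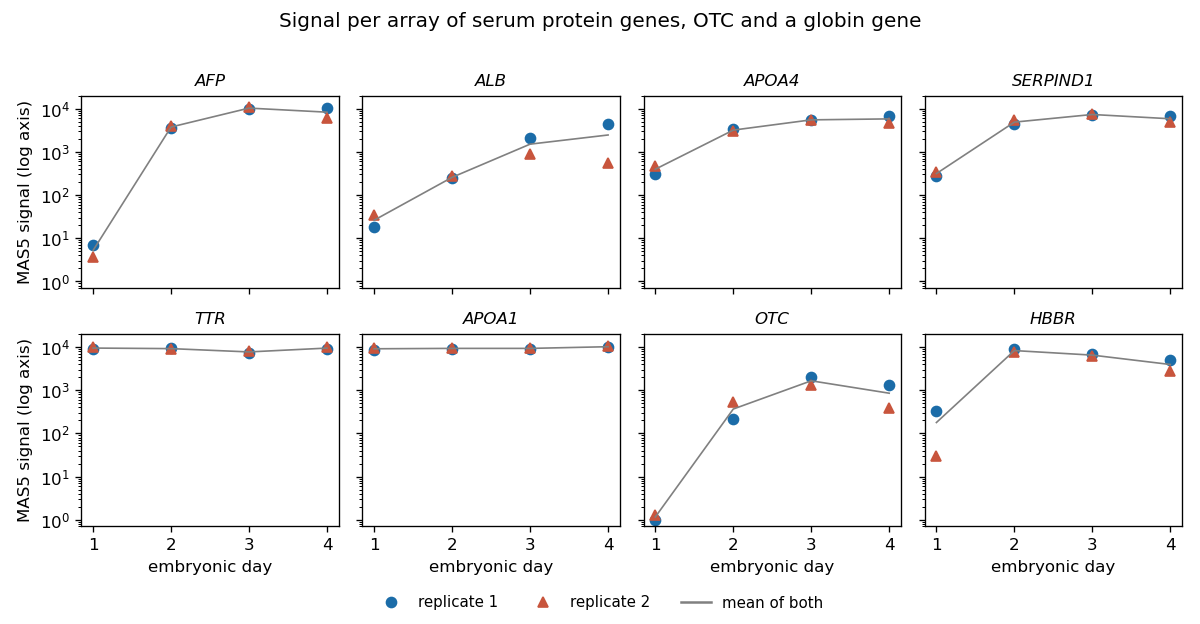
Deposited signal (log axis, arbitrary units) of 8 genes against embryonic day, with a point for each of the 2 arrays of a day and a line through their mean. AFP, SERPIND1, APOA4 and OTC were already far above day 1 on day 2, TTR and APOA1 stayed near the top of the scale, ALB differed between the 2 arrays of day 4 (4366 and 565), and the globin gene HBBR was highest on day 2.

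Genes of lipid handling moved in both directions. In the list for lipid uptake, synthesis and lipoprotein assembly, 12 of 44 members rose and 7 fell, adjusted over the list alone 13 rose and 7 fell, and after quantile normalization 18 rose and 3 fell. FABP7, which encodes a fatty acid-binding protein, rose from 1130 ± 338 to 6106 ± 494 and SCARB1, for a lipoprotein receptor, from 442 ± 20.6 to 2479 ± 967, while FABP5 fell from 136 ± 62.4 to 6.14 ± 2.58. The list shifted up against other genes (camera adjusted p = 1.5e-07, adjusted p = 0.75 with an estimated correlation). Among 14 genes of cholesterol synthesis 9 fell and 0 rose, adjusted over the list alone 10 fell, and after quantile normalization 3 fell and 1 rose. FDPS changed by -3.32 ± 0.49, SQLE by -3.04 ± 0.54 and HMGCS1 by -2.28 ± 0.38, which are enzymes of that pathway. The cholesterol list was not set apart from other genes by camera (adjusted p = 0.13).

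Lists of endocytosis, sugar metabolism and detoxification also shifted up against other genes. Of 25 genes of lysosome and endocytosis 6 rose and 2 fell, also when adjusted over the list alone, and 16 rose and 0 fell after quantile normalization (camera adjusted p = 5.1e-06, adjusted p = 0.75 with an estimated correlation). DAB2, an adaptor for endocytosis of megalin and related receptors, rose by 2.43 ± 0.44, while LIPA, for lysosomal acid lipase, fell by 2.87 ± 0.74 as deposited and missed the threshold after quantile normalization (adjusted p = 0.078). In gluconeogenesis and glycogen metabolism 5 of 14 rose and 1 fell, also when adjusted over the list alone, and 7 rose and 1 fell after quantile normalization (camera adjusted p = 2.2e-05, adjusted p = 0.75 with an estimated correlation). PCK1 rose from 187 ± 24.7 to 1605 ± 526 and FBP1 from 2456 ± 507 to 8863 ± 855, which encode committed enzymes of gluconeogenesis, and GYG1, which primes glycogen, fell by 1.99 ± 0.40. Of 30 genes of detoxification and redox 7 rose and 8 fell, adjusted over the list alone 7 rose and 9 fell, and after quantile normalization 11 rose and 3 fell. That list had a median of -0.04 and a mean of 0.02 (camera up, adjusted p = 0.0046, adjusted p = 0.79 with an estimated correlation). ADH1C rose by 4.49 ± 0.82 and SOD3 by 2.77 ± 0.38, while PRDX1 fell by 1.76 ± 0.30.

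Among 18 endoderm and hepatic transcription factors, CEBPB and PROX1 rose, and SOX17, GATA5, HHEX and XBP1 fell, with the same counts adjusted over the list alone. After quantile normalization 8 rose and 2 fell. GATA5 changed by -4.87 ± 0.41 and PROX1 by 1.17 ± 0.36, and SOX17, at -2.88 ± 0.93, missed the threshold after quantile normalization (adjusted p = 0.16). Their median change was 0.19 and their mean -0.56. The camera shift was up (adjusted p = 0.029) but was lost after quantile normalization (adjusted p = 0.14) and with an estimated correlation (adjusted p = 0.75 with an estimated correlation). Absorptive transporters and peptidases were split, with 5 of 25 higher and 6 lower, 6 and 6 adjusted over the list alone, and 7 and 4 after quantile normalization. The brush border peptidase genes DPP4 and ANPEP rose by 2.04 ± 0.25 and 2.17 ± 0.36, while MME, for neprilysin, changed by -3.78 ± 0.39. The median of that list was -0.16 while camera placed it up against other genes (adjusted p = 0.029, after quantile normalization 0.14, adjusted p = 0.75 with an estimated correlation).

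All 32 measured cell cycle genes fell, also when adjusted over the list alone, and 28 fell after quantile normalization. TOP2A, for topoisomerase II alpha, went from 985 ± 205 to 122 ± 68.3, KIF20A changed by -3.68 ± 0.54, CENPE by -3.27 ± 0.49 and CCNB3 by -3.11 ± 0.44. The median change of the list was -2.95 (camera adjusted p = 1.5e-09, adjusted p = 0.75 with an estimated correlation). Of 17 genes of primitive streak and hypoblast 13 fell and 0 rose, also when adjusted over the list alone, and 8 fell after quantile normalization (camera adjusted p = 0.013, adjusted p = 0.75 with an estimated correlation). TBXT, the mesoderm factor Brachyury, changed by -3.77 ± 0.56, BMP7 by -3.19 ± 0.51, BMP2 by -3.05 ± 0.50 and WNT5A by -2.46 ± 0.44. Of 13 pluripotency and epiblast genes 6 fell, LIN28A by 2.91 ± 0.47 among them, and EPCAM rose, with 2 higher and 6 lower adjusted over the list alone and 2 higher and 4 lower after quantile normalization (camera adjusted p = 0.96).

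Secreted vascular regulators were mixed, with AGT, SERPINF1, TIMP3 and VTN higher and 9 of 27 lower. Adjusted over the list alone 5 were higher and 13 lower, and after quantile normalization 7 and 2 (camera adjusted p = 0.26). AGT, for angiotensinogen, rose by 3.84 ± 0.36 and SERPINF1, for the angiogenesis inhibitor PEDF, by 2.34 ± 0.41. Genes of the ER and secretory pathway had 1 member higher (CREB3L3) and 15 of 33 lower, also when adjusted over the list alone, and 2 higher and 5 lower after quantile normalization (camera adjusted p = 0.64). The chaperone gene HSPA5 changed by -1.09 ± 0.22. In oxidative phosphorylation 7 of 34 fell, 5 adjusted over the list alone, and after quantile normalization 2 fell and 1 rose (camera adjusted p = 0.96), with CYCS, for cytochrome c, at -2.11 ± 0.32.

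Markers of other cell types were lower or mixed on day 4. As deposited, 3919 of all 10553 genes also had a fallen probe set, and the median change over all genes was -0.66. After quantile normalization 1874 genes had a fallen probe set. A count of falls alone therefore does not set a marker list apart. Of 18 primitive erythroid markers 6 rose and 6 fell, also when adjusted over the list alone, and 6 rose and 3 fell after quantile normalization. Their median was -0.28 while camera placed them up (adjusted p = 0.021, after quantile normalization 0.37, adjusted p = 0.79 with an estimated correlation). Of 19 endothelial markers 10 fell and 0 rose, 11 fell adjusted over the list alone, and after quantile normalization 5 fell and 2 rose (camera adjusted p = 0.26). The fall of CDH5, for VE-cadherin, from 725 ± 245 to 4.35 ± 5.65, was not called after quantile normalization (adjusted p = 0.068). Of 30 mesoderm, mesothelium and smooth muscle markers 15 fell and 1 rose, 18 and 1 adjusted over the list alone, and after quantile normalization 8 fell and 2 rose (camera adjusted p = 0.13, after quantile normalization 0.010, and on that scale adjusted p = 0.67 with an estimated correlation). VIM, for vimentin, changed by -2.53 ± 0.63 (adjusted p = 0.010, after quantile normalization 0.061), and COL3A1, for a fibrillar collagen, was at 68.1 ± 22.3 and 38.0 ± 11.9 (adjusted p = 0.79). Of 10 leukocyte markers CYBB and RUNX1 fell, also when adjusted over the list alone, against 2 higher and 1 lower after quantile normalization (camera adjusted p = 0.22). Of 16 ectoderm markers 6 fell, 7 adjusted over the list alone, against 2 higher and 2 lower after quantile normalization (camera adjusted p = 0.96). Of 7 neural markers 5 fell, also adjusted over the list alone, and 3 after quantile normalization, with NEFM, a neurofilament gene, at -4.06 ± 0.34 (camera adjusted p = 0.12).

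Over all probe sets, 790 were higher and 6344 lower on day 4 than on day 1, so that 11.1% of the calls were rises. After quantile normalization 2492 were higher and 2763 lower, 47.4% rises, and 787 rises and 2757 falls were called on both scales. With each array shifted to the same median, 3124 were higher and 2599 lower, 54.6% rises. Scaling by hybridization controls gave 797 higher and 4131 lower (16.2% rises; 680 and 521 without day 1 replicate 2) and by poly-A controls 603 and 6743 (8.21% rises; 549 and 1523 without day 1 replicate 2), so which direction held the majority depended on the scaling. Without day 1 replicate 2 the calls came to 557 higher and 1128 lower, and without day 4 replicate 1 to 357 higher and 2034 lower. Without day 1 replicate 2 there were also 21 rises among the serum protein genes, 11 falls among the cell cycle genes, 4 among 13 measured of the streak genes, 2 among the cholesterol genes, 1 among the endothelial and 5 among the mesoderm markers. Of the 10 list calls 7 held with each array left out in turn, and those of the transcription factors, the absorptive genes and the erythroid markers did not (adjusted p = 0.11, 0.052 and 0.15 without day 1 replicate 2).

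Between day 1 and day 2 the largest rises included the plasma protein gene AFP and the globin genes HBBR, HBZ and HBE. AFP rose from 5.24 ± 2.33 to 3769.8 ± 188, a log2 change of 7.48 ± 0.30 (adjusted p = 1.9e-08). The globin genes HBBR, HBZ, HBE and HBA1 rose by 6.04 ± 0.64, 4.76 ± 0.56, 4.64 ± 0.48 and 4.02 ± 0.40, and SLC4A1, the anion exchanger of the red cell membrane, by 4.46 ± 0.52. AQP8, a water channel gene, rose from 64.5 ± 51.3 to 2525 ± 1373, PTGDS by 4.79 ± 0.53 and SLC12A1, for a sodium-potassium-chloride cotransporter, by 4.52 ± 0.70. The largest falls were those of CDX4 (-6.72 ± 0.43), the astacin protease gene ASTL (-5.93 ± 0.65), BHLHE22 (-5.06 ± 0.40), the muscle light chain gene MYL3 (-4.66 ± 0.55), CLEC19A (-4.55 ± 0.37), TGFBI (-4.47 ± 0.73), AGRP (-4.33 ± 0.41) and TNNT2, for cardiac troponin T (-4.12 ± 0.35). CDX4, MYL3 and AGRP had means of 3.43, 5.01 and 7.40 on day 2. AFP, SLC12A1 and SLC4A1 had means of 5.24, 5.71 and 6.77 on day 1. The sizes and ranks of these changes therefore depend on the 16 added. Whether the falls of the muscle genes MYL3 and TNNT2 came from endoderm or from other cells present on day 1 was not tested.

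Of the 34 serum protein genes 22 rose and 0 fell from day 1 to day 2. Adjusted over the list alone 26 rose, and after quantile normalization 27 rose. Their median log2 change was 2.00, against -0.44 over all genes (camera adjusted p = 3.8e-40, adjusted p = 0.32 with an estimated correlation). SERPIND1 rose by 3.89 ± 0.25, GC by 3.99 ± 0.42 and APOA4 by 2.99 ± 0.28. Red cell markers moved with this group, with 7 of 18 erythroid markers higher and 0 lower, 7 higher and 2 lower adjusted over the list alone, and 7 higher after quantile normalization (camera adjusted p = 2.2e-08, adjusted p = 0.61 with an estimated correlation). HBZ reached 9373 ± 1931 and HBA1 8778 ± 1990.1. Lipid genes had 8 of 44 higher and 1 lower, 14 and 5 adjusted over the list alone, and 15 and 1 after quantile normalization (camera adjusted p = 5.2e-07, adjusted p = 0.61 with an estimated correlation). MOGAT1, an acyltransferase of triglyceride synthesis, rose by 2.37 ± 0.32, SCARB1 by 2.09 ± 0.33, and the fall was that of FABP5 (-2.59 ± 0.36). In gluconeogenesis and glycogen PCK1, FBP1 and PCK2 rose, by 2.73 ± 0.32, 1.91 ± 0.21 and 1.73 ± 0.34, and no member fell. The counts were 4 higher and 1 lower adjusted over the list alone and 6 higher after quantile normalization (camera adjusted p = 0.00013, adjusted p = 0.61 with an estimated correlation).

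In detoxification and redox SOD3, MT3, EPHX1 and GSTT1 rose and no gene fell, with 7 higher and 2 lower adjusted over the list alone and 10 higher after quantile normalization (camera adjusted p = 5.1e-05, adjusted p = 0.63 with an estimated correlation). SOD3 rose by 2.65 ± 0.38 and the metallothionein gene MT3 from 3374 ± 898 to 8013 ± 1119. Of the lysosome and endocytosis genes DAB2 alone rose, by 2.24 ± 0.44, also when adjusted over the list alone, and 4 rose after quantile normalization (camera adjusted p = 1.6e-05, adjusted p = 0.61 with an estimated correlation). Among absorptive genes ANPEP, DPP4 and CALB1 rose and SLC2A1 and ATP2B1 fell, with 3 higher and 3 lower adjusted over the list alone and 4 higher and 2 lower after quantile normalization. SLC2A1, for a glucose transporter, went from 3372 ± 1396 to 313 ± 145. That list was up in camera with a median of -0.20 (adjusted p = 0.016, after quantile normalization 0.067, adjusted p = 0.63 with an estimated correlation). Of the endoderm transcription factors GATA5 (-2.51 ± 0.41) and HHEX (-3.63 ± 0.96) fell, HHEX not after quantile normalization (adjusted p = 0.11). Adjusted over the list alone 1 factor was higher and 2 lower, and after quantile normalization 1 was higher and 1 lower, with a median of -0.03 and a mean of -0.40 while camera pointed up (adjusted p = 0.26).

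Streak genes fell in 9 of 17 cases, 11 adjusted over the list alone and 6 after quantile normalization (camera adjusted p = 0.00011, adjusted p = 0.61 with an estimated correlation), with TBXT at -4.11 ± 0.56 and WNT5A at -2.75 ± 0.44. Of the pluripotency genes SOX3, LIN28A, DDX4 and SALL4 fell, 6 fell adjusted over the list alone and 3 after quantile normalization (camera adjusted p = 0.16). The cell cycle genes CCNE1 and TOP2A fell and none rose, 20 of 32 fell adjusted over the list alone, and 0 passed after quantile normalization. The median of the cell cycle list was -1.32 (camera adjusted p = 0.00011, adjusted p = 0.67 with an estimated correlation). In cholesterol synthesis FDPS fell, 8 of 14 fell adjusted over the list alone, and 0 passed after quantile normalization (camera adjusted p = 0.035, adjusted p = 0.67 with an estimated correlation). AGT, TIMP3 and SERPINF1 rose among the secreted vascular regulators and BMP2 and CXCL12 fell, with 4 higher and 3 lower adjusted over the list alone and 4 higher and 1 lower after quantile normalization (camera adjusted p = 0.16). No gene of the ER pathway or of oxidative phosphorylation passed the limma test, also when adjusted over the list alone, and 1 ER gene rose after quantile normalization (camera adjusted p = 0.38 and 0.18).

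Mesoderm and endothelial markers differed between the 2 arrays of day 2. COL3A1 had signals of 4601 on replicate 1 and 29.6 on replicate 2, and CDH5 1147 and 7.43, so that COL3A1 at 2315 ± 3233 did not differ from day 1 by more than this spread (adjusted p = 0.31). Of the mesoderm markers 7 of 30 fell and 0 rose, 8 and 1 adjusted over the list alone, and 5 and 1 after quantile normalization (camera adjusted p = 0.92). KDR fell among the 19 endothelial markers, 4 fell adjusted over the list alone and 0 after quantile normalization (camera adjusted p = 0.36). The leukocyte markers CYBB and RUNX1 fell, also when adjusted over the list alone, and 0 passed after quantile normalization (camera adjusted p = 0.26). The ectoderm markers DLX5 and MSX1 fell, 4 of 16 fell adjusted over the list alone and 3 after quantile normalization (camera adjusted p = 0.25). The neural markers NEFM and ELAVL4 fell, 4 of 7 adjusted over the list alone and 2 after quantile normalization (camera adjusted p = 0.031, adjusted p = 0.67 with an estimated correlation).

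**Figure D2:**
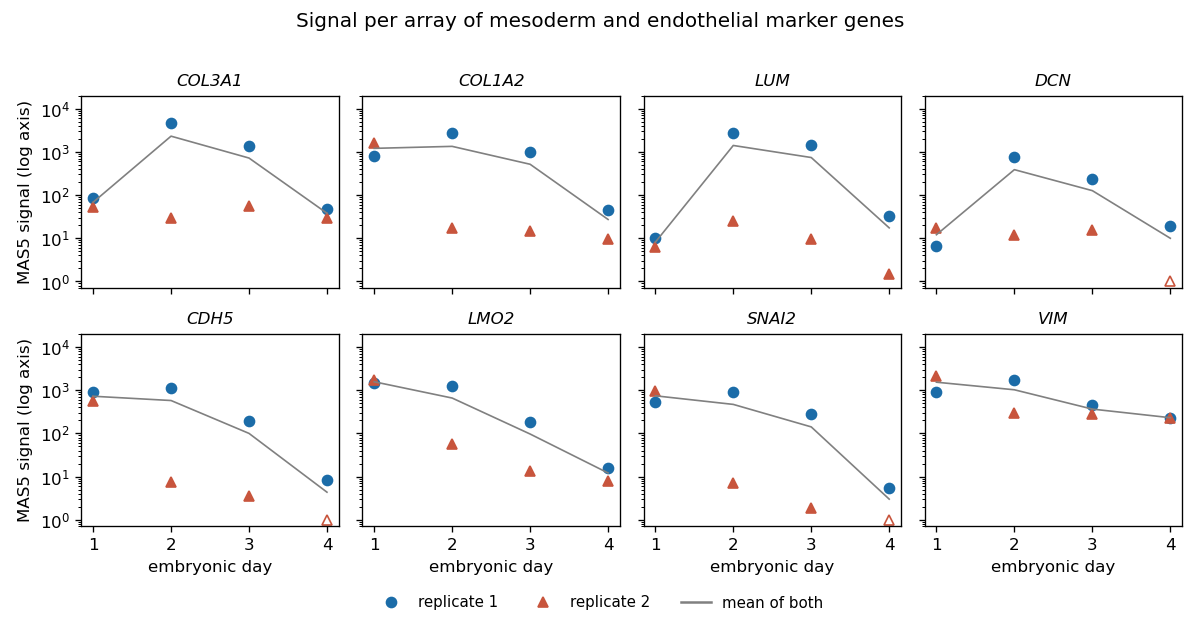
Deposited signal (log axis, arbitrary units) of 8 mesoderm and endothelial genes against embryonic day, with a point for each array and a line through the mean of the 2 arrays of a day; open symbols mark signals below 1, drawn at 1. Replicate 1 lay far above replicate 2 on days 2 and 3 in COL3A1, LUM, DCN and CDH5, and both replicates of these genes were low on day 4.

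In total 371 probe sets were higher and 860 lower on day 2 than on day 1, and 884 and 522 after quantile normalization, so that the share of rises went from 30.1% to 62.9%; 366 rises and 457 falls were called on both scales. The share of rises was 69.4% with each array shifted to the same median (997 higher, 439 lower), 50.7% with scaling by hybridization controls (476 and 462) and 63.2% with poly-A controls (532 and 310). The count was 222 without day 1 replicate 2 (169 higher, 53 lower), 5659 without day 1 replicate 1, 2774 without day 2 replicate 1 and 700 without day 2 replicate 2. Without day 1 replicate 2 11 serum protein genes rose and 1 streak gene fell. With replicate 1 of days 2 and 3 left out, 11 endothelial and 15 mesoderm markers fell. Of the 11 list calls 7 held with each array left out in turn, and those of the cell cycle (adjusted p = 0.057 without day 1 replicate 1), cholesterol synthesis (0.13 without day 1 replicate 1, 0.11 without day 2 replicate 2), absorptive genes (0.11 without day 2 replicate 2) and neural markers (0.12 without day 1 replicate 2) did not.

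Between day 2 and day 3 serum protein genes were again higher in their means and cell cycle genes lower, but no single probe set passed. ITIH2 had 762 ± 168 on day 2 and 3529 ± 135 on day 3 (log2 change 2.20 ± 0.31, adjusted p = 0.16), and AFP 3769.8 ± 188 and 10333 ± 501 (adjusted p = 0.35). The prothrombin gene F2 had 678 ± 77.0 and 2112 ± 377, and FETUB, for fetuin B, 570.5 ± 115 and 2463 ± 142. CDC20, an activator of the anaphase-promoting complex, had 755 ± 27.0 and 151 ± 52.9, and CCNE2, for cyclin E2, 177 ± 18.0 and 14.1 ± 3.53. PCK1 had 1335 ± 255 and 3025 ± 372, and HBZ 9373 ± 1931 and 7472 ± 585.

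Adjusted over the list alone, 9 of 34 serum protein genes rose and 1 fell, and after quantile normalization 15 rose and 2 fell adjusted over the list alone, with a median of 0.81 (camera adjusted p = 1.8e-13, adjusted p = 0.86 with an estimated correlation). Of the cell cycle genes 26 of 32 fell adjusted over the list alone, and 28 did so after quantile normalization, with a median of -1.66 (camera adjusted p = 1.0e-23, adjusted p = 0.86 with an estimated correlation). The erythroid markers shifted down with a median of -0.90 (adjusted p = 0.00013), and so did the cholesterol genes (adjusted p = 0.017, after quantile normalization 0.074) and the endothelial markers (median -0.90, adjusted p = 0.028, after quantile normalization 0.14). The endothelial direction was set by the arrays of day 2, with a median of 0.38 without replicate 1 and -2.28 without replicate 2, and the erythroid median was -0.18 without replicate 1 of day 2 (adjusted p = 0.21). Lipid genes (adjusted p = 0.00062), gluconeogenesis genes (adjusted p = 0.0092) and lysosome genes (adjusted p = 0.0098) shifted up. With each array left out in turn only the calls of the serum protein and cell cycle lists held, and those of the lipid and lysosome genes were lost without day 2 replicate 1 (adjusted p = 0.083 and 0.19), as was that of cholesterol synthesis (0.15), and that of gluconeogenesis without day 3 replicate 2 (0.059). None of these 8 list calls held with an estimated correlation (adjusted p = 0.86 to 0.96 with an estimated correlation). The gluconeogenesis list had 1 member higher and the absorptive list 1 lower adjusted over the list alone, and the other lists 0. After quantile normalization and adjusted over the list alone these counts were 4 higher and 1 lower for lipid genes, 3 and 2 for detoxification, 1 higher each for gluconeogenesis, lysosome and leukocyte lists, and 1 lower each for absorptive and cholesterol genes. For the 12 other lists camera gave an adjusted p between 0.10 and 0.92. CDH5 had signals of 196 and 3.62 on the 2 arrays of day 3 and COL3A1 1386 and 56.5.

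By limma 0 of 23063 probe sets passed on day 3 against day 2, with 1663 at an unadjusted p under 0.05 and a smallest adjusted p of 0.16, and 0 after quantile normalization, with 2950 at an unadjusted p under 0.05. Without day 2 replicate 2, 601 passed (46 higher, 555 lower), without day 4 replicate 1, 13, without day 4 replicate 2, 8, without day 3 replicate 2, 5, and without day 2 replicate 1 or day 3 replicate 1, 1 each.

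Between day 3 and day 4 differences were smaller, and no single probe set passed. CD36, for a fatty acid translocase, had 585 ± 87.3 on day 3 and 76.5 ± 52.2 on day 4 (log2 change -2.82 ± 0.43, adjusted p = 0.23). PROX1, a homeobox gene of hepatoblasts and lymphatic endothelium, had 18.8 ± 0.71 and 78.0 ± 34.8 (adjusted p = 0.74), and the serpin gene SPIA1 3698 ± 570.0 and 1436 ± 1150.2 (adjusted p = 0.91). HBZ had 7472 ± 585 and 3789 ± 1626, and AGT 3421 ± 247 and 1957 ± 134.

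Adjusted over the list alone, CD36 fell in the lipid list and PROX1 rose among the transcription factors, on both scales, and 0 members passed in the other 18 lists as deposited, while after quantile normalization 2 absorptive genes fell. The camera test placed serum protein genes down (median -0.32, adjusted p = 0.0041), together with erythroid markers (median -0.77, adjusted p = 0.020), absorptive genes (adjusted p = 0.024), endothelial markers (median -0.66, adjusted p = 0.037), mesoderm markers (median -0.56, adjusted p = 0.038) and oxidative phosphorylation (adjusted p = 0.038). It placed cholesterol synthesis up (median 0.17, adjusted p = 0.0041), with the cell cycle (median 0.06, adjusted p = 0.018), streak genes (adjusted p = 0.018) and transcription factors (adjusted p = 0.033). The cell cycle direction was set by the arrays of day 4, with a median of 0.77 without replicate 1 and -0.72 without replicate 2. The serum protein median was -0.70 without day 4 replicate 1 and -0.10 without day 4 replicate 2 (adjusted p = 0.42), and without day 3 replicate 1 the endothelial and mesoderm calls were lost (adjusted p = 0.73 and 0.45). With each array left out in turn only the call of cholesterol synthesis held; without day 4 replicate 2 the others had an adjusted p of 0.45 (erythroid and absorptive), 0.22 (oxidative phosphorylation), 0.10 (transcription factors) and 0.063 (streak). None of these 10 calls held with an estimated correlation (adjusted p = 0.87 with an estimated correlation in each), and after quantile normalization 4 were left, those of serum proteins, cholesterol synthesis, endothelial and mesoderm markers. For the 10 other lists the camera adjusted p lay between 0.055 and 0.86.

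By limma 0 of 23063 probe sets passed on day 4 against day 3, with 915 at an unadjusted p under 0.05 and a smallest adjusted p of 0.23, and 0 after quantile normalization, with 1418 at an unadjusted p under 0.05. The count was 10 without day 2 replicate 1, 10 without day 2 replicate 2, 1 without day 3 replicate 1, 9 without day 3 replicate 2, 11 without day 4 replicate 1 and 3 without day 4 replicate 2.

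**Figure D3:**
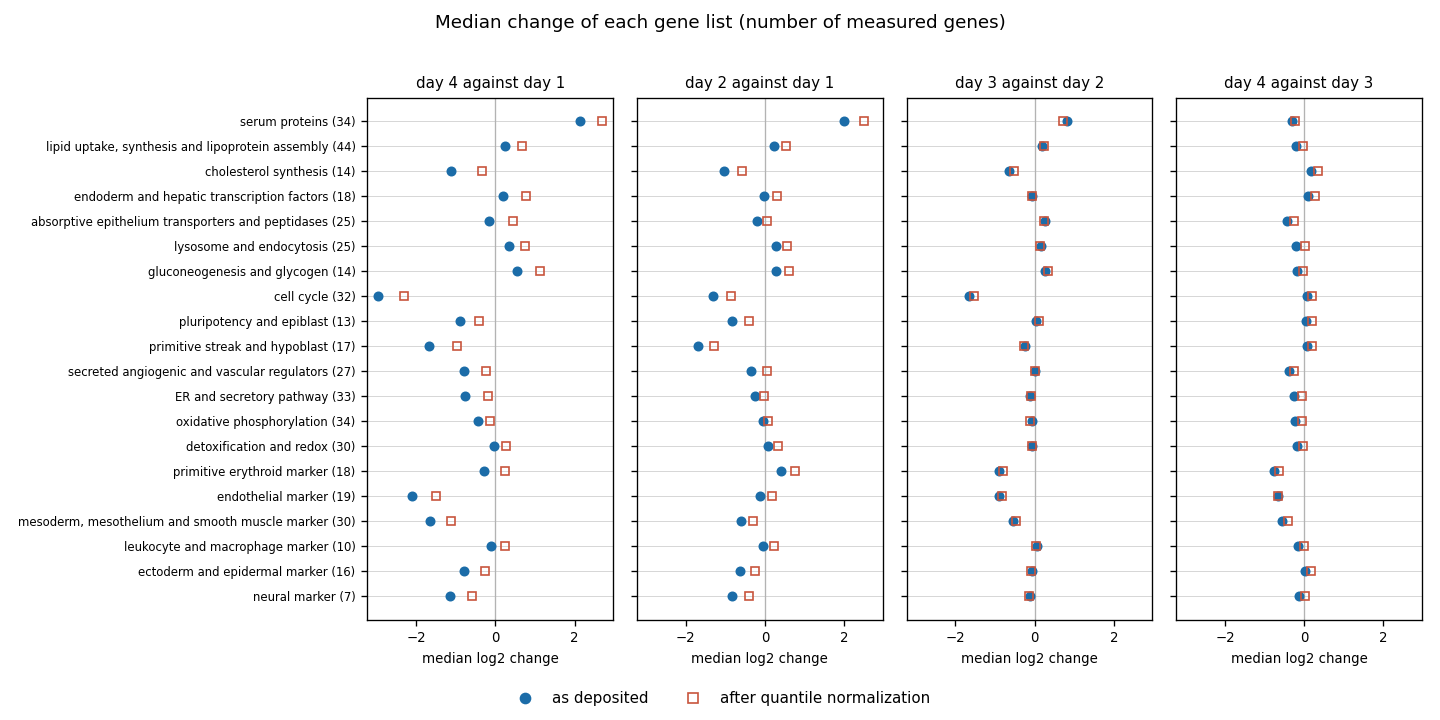
Median log2 change of 20 gene and marker lists in 4 comparisons, as deposited (filled circles) and after quantile normalization (open squares), with the number of measured genes in brackets. Serum protein genes had the highest median on day 4 against day 1 (2.13) and cell cycle genes the lowest (-2.95), and all 20 lists lay higher after quantile normalization in the comparisons with day 1.

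Across the 4 days, 4789 of 23063 probe sets differed by the moderated F-test, and 3981 after quantile normalization. The highest mean fell on day 1 for 3888 of them (81.2%), on day 3 for 669, on day 4 for 143 and on day 2 for 89. After quantile normalization day 1 was highest for 48.9%, day 3 for 30.3%, day 4 for 17.8% and day 2 for 2.96%. Among the named genes AFP and the serum protein gene TF, for transferrin, had their highest means on day 3, TF with signals of 2933 and 3916 on day 1 and 9939.8 and 11152 on day 3, and the globin genes on day 2. Without day 1 replicate 2, 309 probe sets differed.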

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

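Scaling by controls, quantile normalization joined to array removal and the removal of replicate 1 of days 2 and 3 together were tests chosen only after the data were seen. Of 337 values of named genes, none that passed the threshold as planned or under an alternative changed direction between the 2. A change of direction was not counted where a value passed in neither. In the analysis as planned 127 values passed. Of these, 64 passed in the same direction under every alternative run and 81 under every alternative that held all 8 arrays. Without day 1 replicate 2, 49 of these values no longer passed, without day 4 replicate 1, 15. Where a day is left with 1 array, that array is assumed to vary like those of the other days.

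For day 4 against day 1 the 7134 calls became 3785 with array weights and 1447 after quantile normalization with the brightest day 1 array left out, and with single arrays left out they ranged from 1685 without day 1 replicate 2 to 10173 without day 1 replicate 1. For day 2 against day 1 the 1231 calls became 618 with a pseudocount of 1, 443 without a filter, 198 with array weights, 226 after quantile normalization with the brightest day 1 array left out, and 1893 with replicate 1 of days 2 and 3 left out. With single arrays left out they ranged from 222 without day 1 replicate 2 to 5659 without day 1 replicate 1.

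For day 3 against day 2 the count of 0 became 28 with scaling by hybridization controls, 35 with poly-A controls and 17 with replicate 1 of days 2 and 3 left out, and with single arrays left out it ranged from 0 to 601, the latter without day 2 replicate 2. For day 4 against day 3 it became 6, 13 and 8 under the same alternatives, and 0 to 11 with single arrays left out. The 4789 probe sets of the F-test became 2377 without a filter, 1721 with array weights and 409 after quantile normalization with the brightest day 1 array left out, and with single arrays left out 309 without day 1 replicate 2 to 6616 without day 2 replicate 2.

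Lists called came to 10, 11, 8 and 10 in the 4 comparisons, and to 0, 0, 0 and 0 with an estimated correlation. For day 3 against day 2 they came to 5 with replicate 1 of days 2 and 3 left out, and to 3 when quantile normalization was added. For day 4 against day 3 they came to 4 after quantile normalization, 5 with the brightest day 1 array also left out, 4 with replicate 1 of days 2 and 3 also left out, and 2 to 10 with single arrays left out, 2 without day 4 replicate 2.

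Some list directions, which camera takes relative to other genes, reversed. Without replicate 1 of day 2 the medians for day 2 against day 1 were -1.93 for endothelial and -1.60 for mesoderm markers, and without replicate 2 of day 2 they were 0.62 and 0.34. With replicate 1 of days 2 and 3 left out they were -1.93 and -1.59, and -1.34 and -1.14 after quantile normalization. For day 3 against day 2 the medians were 0.38 for endothelial and 0.45 for mesoderm markers without day 2 replicate 1, and -2.28 and -1.66 without day 2 replicate 2; that of the transcription factors was -0.15 with replicate 1 of days 2 and 3 left out. For day 4 against day 3 the median of the endothelial markers was -0.092 without day 3 replicate 1 and -1.15 without day 3 replicate 2, and that of the mesoderm markers -0.053 and -0.75. The mesoderm median was -0.0804 with replicate 1 of days 2 and 3 left out and -0.00267 after quantile normalization. Without day 4 replicate 1 the serum protein median was -0.70 and the cell cycle median 0.77, and without day 4 replicate 2 they were -0.10 and -0.72. Apart from the alternatives that test fewer arrays, the cause was not tested.

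With the replicate number as a replicate block the counts were 6607, 884, 0 and 0 in the 4 comparisons and 4076 in the F-test, with 10, 11, 8 and 11 lists called. The deviations of replicate 1 from the mean of its day correlated at -0.14 to 0.10 in 5 of the 6 pairs of days and at 0.39 between days 2 and 3. Same-numbered arrays thus deviated together on days 2 and 3 but not across all days, and the labels do not say that a number marks a shared batch. Low signals limit what can be called, since the median signal was 11.8 to 26.0 by array, near the 16 added before the logarithm.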

Other observations

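The gene families below and all tests of explanations were chosen only after the results were seen; the splits of the arrays were planned. OTC and CPS1, for enzymes of the urea cycle, were among the 8 largest rises from day 1 to day 4. Transcript levels do not show whether the tissue made urea. OTC, CPS1, ASS1 and ASL rose and the arginase gene ARG2 fell, that is 4 higher and 1 lower among 5 measured, and 3 and 1 after quantile normalization. The list was made because of OTC and CPS1, so no test of it is given. ASL, with signals of 104 and 7.01 on the arrays of day 4, missed the threshold after quantile normalization (adjusted p = 0.078), and ASS1 changed by 2.68 ± 0.25 and ARG2 by -3.62 ± 0.46. Of 14 complement genes C1R, C1S, C8G, MASP2 and C5 rose and 0 fell by limma, and 6 rose after quantile normalization. Camera gave an adjusted p of 7.0e-06, and 0.18 with an estimated correlation. These values are descriptive, since that list too was chosen after the results were seen.

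Most proteasome and ribonucleoprotein genes fell on both scales. For comparison, 3919 of all 10553 genes had a fallen probe set as deposited and 1874 after quantile normalization. The families below were chosen after the results were seen. Their camera values, adjusted over 7 such families, are therefore descriptive and not tests. Of 29 proteasome subunit genes 24 fell, and 19 after quantile normalization (camera adjusted p = 0.00014, adjusted p = 0.66 with an estimated correlation). Of 13 genes of heterogeneous nuclear ribonucleoproteins 12 fell, and 11 after quantile normalization (adjusted p = 0.0049, adjusted p = 0.66 with an estimated correlation). Of 43 translation initiation factor genes 25 fell, and 18 fell and 1 rose after quantile normalization (adjusted p = 0.0093, adjusted p = 0.76 with an estimated correlation). Of 17 HOX genes 9 fell, and 6 after quantile normalization. Camera gave an adjusted p of 0.16 as deposited and 0.0497 after quantile normalization. With an estimated correlation these were 0.76 and 0.55. Of 66 ribosomal protein genes 1 rose and 4 fell, and 1 and 7 after quantile normalization, with camera pointing up as deposited and down after quantile normalization (adjusted p = 0.12 and 0.15).

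Most probe sets called between day 1 and day 4 were lower on day 4 as deposited. The brightness of the arrays after hybridization stays open: 27 hybridization control probe sets changed by -0.15 where the median of the arrays changed by -0.71, but without day 1 replicate 2 the values were -0.25 and -0.39, so the controls reached 63.98% of the change. Scaling by these controls left 4131 of the calls lower and 797 higher, but 521 lower and 680 higher without day 1 replicate 2. Weaker labelling of the RNA on day 4 was excluded as the whole cause, if poly-A controls were added to the RNA in equal amounts, since 36 such probe sets changed by 0.11, and by 0.03 without day 1 replicate 2. Poly-A controls were hybridized to the same arrays and argue against brightness only on that assumption, which no value here tests. The share of mRNA in total RNA, RNA integrity and the RNA amount in each reaction were not tested and stay open. So does a biological loss of many transcripts.

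Mesoderm and endothelial markers were higher in replicate 1 than in replicate 2 of days 2 and 3. Primitive erythroid markers were also higher in replicate 1, by a median of 1.40 on day 2 (percentile 100 of 10000 random lists) and 0.14 on day 3 (percentile 97.6). They were likewise higher by 0.41 on day 1 and 0.45 on day 4, both at percentile 100. The endothelial list lay at percentile 99.87 on day 1, with a median of -0.23 against -0.57 for random lists. On day 4 it lay at percentile 97.2, with a median of 0.15. The mesoderm list lay at percentiles 42 and 87.9 on days 1 and 4. Serum protein genes also reached percentile 100 on day 4, so a high percentile was not particular to these markers. An array-wide difference in brightness was excluded, since the mesoderm and endothelial lists both lay at percentile 100 of 10000 random lists on day 3. A younger average stage of replicate 1 of day 2 was not excluded. There, 32.7% of the marker genes (16 of 49) lay more than 2-fold above both day 1 arrays and replicate 2 of day 2. The share was 1.24% of other genes. These values argue against a steady course between day 1 and replicate 2 of day 2. Genes that peak in between would also give them. Stage was not tested for day 3. Cells of the mesodermal layer carried along in replicate 1 may be the source, but were not told apart from other differences that both days share. Of 196 genes outside the lists at least 4-fold higher in replicate 1 of day 2, 96.9% were higher in replicate 1 of day 3. For random genes the median share was 54.6% and the highest 67.3%. This shows that replicate 1 of both days deviated alike. It does not show that the 196 genes are mesodermal. COL3A1 reached 4601 and LUM 2796 in replicate 1 of day 2, and dispase separation would remove such cells where it was complete. The 3' to 5' ratio of beta-actin was lower in replicate 1, 1.74 against 3.77 on day 2 and 2.63 against 3.36 on day 3. That of EF1A was lower on day 2 (1.84 against 2.19) and higher on day 3 (1.95 against 1.75). A part of RNA integrity in this pattern was not tested.

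Serum protein genes were higher on day 4 than on day 1. A larger share of endoderm cells in the later samples was not excluded. The endoderm and hepatic transcription factors had a median change of 0.19 (95% interval -0.54 to 0.62). The serum protein genes had 2.13 (1.27 to 2.72). These intervals came from resampling the genes of each list and do not measure the spread between samples. Of the 18 factors 2 rose and 4 fell, with GATA5 at -4.87 and HHEX at -5.94. Their median therefore need not follow the share of endoderm cells. The array-wide level of the arrays was excluded, since 29 serum protein genes were higher after quantile normalization. A rise of serum protein transcripts within the endoderm is a hypothesis for this pattern, and was not told apart from a change in cell share. It was found on the same data. Blood carried along in the later samples was not tested. HBBR had signals of 327 and 29.7 on day 1 and 8968 and 7575 on day 2. They were 6849 and 6131 on day 3 and 5071 and 2805 on day 4.

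Of 105 possible splits of the 8 arrays into 4 pairs, 100 were drawn. Of these, 2 gave at least as many probe sets in the F-test as the days, the days included. That share is under 0.05 for the split as a whole. The days gave 4789 and the highest other split 5606. After quantile normalization it was again 2 of 100, with 3981 and 4220. The other split held the day 1 arrays together and paired replicate 1 of day 2 with replicate 1 of day 3, replicate 2 of day 2 with replicate 2 of day 4, and replicate 2 of day 3 with replicate 1 of day 4, which points to a structure of the samples besides the day. The 14 drawn splits that hold the day 1 arrays together gave 680 to 5606 probe sets (526 to 4220 after quantile normalization), with the days in place 2, and the 86 others at most 87 (6). The result therefore rests on day 1 standing apart, and does not show that days 2, 3 and 4 differ from each other. Since 14 of the 100 drawn splits keep the day 1 arrays together, the splits do not exclude chance at 0.05 for that feature.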
